A study of Mus musculus with 11 samples.

How the data were processed

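RNA was sequenced from 11 organoid cultures of mouse small-intestinal epithelium, 1 library per animal and passage. The labels give the tissue of every library as small intestine, while the protocol text describes dissection of upper and lower small intestine and of colon, and no label gives the part of the intestine for a library. The organoids had been grown in a basement membrane gel with a commercial intestinal medium, and RNA had been extracted with a phenol reagent. The authors deposited read counts per gene for each library, in tables with an unstranded column and a column per strand. Per the submitters' processing notes, reads were trimmed with Trimmomatic and aligned and counted with STAR on mouse genome build mm9. Neither the versions of these tools nor the annotation release were given in the sources used here. The passage number in the name of each deposited table was higher by 1 than that in the sample title in all 11 cases, and the titles were used. No file held a value for a sample outside these 11.

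The first strand column held between 50.0% and 50.2% of the stranded reads. Neither strand column reached the 80% set for a stranded library, so the unstranded column was used. Gene reads per library ran from 15114132 to 28949911, unmapped reads from 4.76% to 10.2%, multimapping reads from 5.92% to 8.78%, reads in no gene from 3.77% to 11.7% and ambiguous reads from 3.11% to 4.03%. The last 4 summary lines of each table gave these shares and were left out of the counts. A limit of 3 counts corresponds to 0.10 to 0.20 CPM per library and covers counting error only, since reads are not independent molecules. No libraries were duplicates of each other, with a smallest chi-square per degree of freedom of 14.4 between any pair. Of 37310 gene identifiers, 32620 were matched to a symbol and 6 shared one. Positions are not given, because the annotation at hand was for a later build than the files.

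Early passage comprised passages 2, 3 and 4 (n = 5) and late passage passages 11, 12 and 13 (n = 6). Late was compared with early with the animal in the model, and mouse_285 with mouse_283 with the stage in the model. The interaction of stage and animal and the stage effect within each animal were tested in models that held those terms. A trend with passage number was tested as a slope shared by both stages. Ages of 4 and 24 months were not compared because no label ties them to an animal. Libraries of the same animal were more alike across stages than libraries of different animals, with median correlations of deviations of 0.11 and -0.14, and 8 of 11 libraries had their best match in the other stage in their own animal.

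Analyses used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and Biostrings 2.70.1. Genes were filtered with edgeR's filterByExpr, which left 14172, normalised by TMM and tested by the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Log2 CPM used a prior count of 2. Principal components were computed on the 500 most variable genes.

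The rules for naming genes, the comparisons, the gene lists and all alternatives except those named below as added were fixed before the data were examined. Named were the 10 genes with the largest rise and the 10 with the largest fall late against early among those past the threshold, with a symbol of the usual kind, at least 5 CPM on average and every late library beyond every early library of the same animal. Between the animals the rule named the 6 largest differences with every library of an animal beyond every library of the other at both stages, and the sex-linked genes. For the interaction it named up to 6 genes past the threshold, of which there were none. It further named up to 4 members with the smallest p per list described, and Lgr5, Olfm4, Mki67, Cdkn2a, Cdkn1a, Dnmt1, Dnmt3a, Dnmt3b, Tet1 and Uhrf1. Some members that the rule named are not reported. Of 785 entries in 37 lists, 773 were found. Lists of at least 5 tested genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Counts per list were also adjusted over the list alone. Because expression followed GC content in some libraries, a correction was added after the values were seen, with offsets from a spline of 5 degrees of freedom per library on GC content and transcript length. These were known for 13709 of the tested genes (96.7%) and came from an annotation of the later build. Other additions made after the values were seen were fits without passages 3 and 4 of mouse_283 and an exact permutation of mean list scores within animals.

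The procedure was tested on simulated data with known changes. For late against early, 32.8%, 94.4% and 96.8% of genes changed by 1, 2 and 3 on the log2 scale were recovered, with 6 false among 155 calls. The interaction test recovered 3.03%, 34.7% and 71.0%, the test within mouse_283 recovered 10.7%, 71.2% and 100%, and that within mouse_285 recovered 4.00%, 66.7% and 92.3%. For the animals 40.0%, 95.0% and 98.8% were recovered. A list lowered by 1 was called in 5 of 5 draws, with 0 of 158 other lists called. Simulated genes were drawn independently, so this does not test the preset correlation on lists whose members vary together. In the real data the interferon list, for example, had an estimated correlation of 0.365. With a simulated GC trend, 186 of 200 changed genes were called with 11 false calls without correction, and 185 of 193 with 5 false calls with it.

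Alternatives were RLE factors, library totals, no low-count filter, a filter at 5 CPM, a strand column, leaving out mitochondrially encoded genes, DESeq2, each library left out in turn, the model without the animal or without the stage, passage as a number, counts summed per animal and stage, passages present in both animals and a log2 fold threshold of 1.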

Results

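The series measured gene expression by bulk RNA sequencing in organoids grown from the small-intestinal epithelium of mice that carry the Lgr5-EGFP-IRES-creERT2 reporter, which marks intestinal stem cells. Organoids are self-organising epithelial cultures that keep crypt-like and villus-like cell types, and these were passaged every 7 days. The design text names culture over many passages, and donor age, as the subjects of the study. The 11 libraries came from 2 animals, named mouse_283 and mouse_285 in the titles. Early libraries were from passages 2, 3 and 4 in mouse_283 and from passages 2 and 4 in mouse_285, which gives n = 5. Late libraries were from passages 11, 12 and 13 of both animals, which gives n = 6. The labels name mice of 4 and 24 months but tie neither age to an animal, so no comparison of ages was made. Each library held between 15114132 and 28949911 reads counted in genes, and between 16535 and 19229 genes had at least 1 read. Gene-level p-values are Benjamini-Hochberg adjusted values from edgeR's quasi-likelihood test over 14172 genes, levels are normalised CPM, which are read counts scaled to library size, and errors of fold changes are standard errors (SE).

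Passage stage was the strongest axis among the most variable genes. Principal component 1 of the 500 most variable genes held 40.1% of the variance and separated all 5 early from all 6 late libraries, and component 2 (18.9%) separated the animals. Over all tested genes component 1 (46.9%) separated neither, and followed the slope of each library's expression on GC content (Spearman's rho -0.95). Component 2 of all genes (15.8%) separated stage, and components 1 to 3 did not separate the animals. With the 2000 most variable genes component 3 (13.2%) separated the animals and component 2 did not. The libraries of passages 3 and 4 of mouse_283 stood apart from the other 9 by a trend with base composition. Their expression rose with the GC content of the gene by 1.04 and 0.832 log2 units per 10 points of GC, against slopes from -0.423 to 0.222 in the others. GC content and transcript length accounted for 56.3% and 51.6% of the variance across genes in these libraries, and for 9.29% to 42.2% in the other 9. Next highest were passage 2 of mouse_283 (42.2%) and passage 11 of mouse_285 (40.6%), with slopes of the other sign. Passage 3 of mouse_283 also had the lowest share of mitochondrially encoded reads, 1.05%, and the highest share of ribosomal protein reads, 14.7%. Counts given below were therefore repeated without these 2 libraries and after a correction on GC content and length, both chosen after seeing the data.

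**Figure D1:**
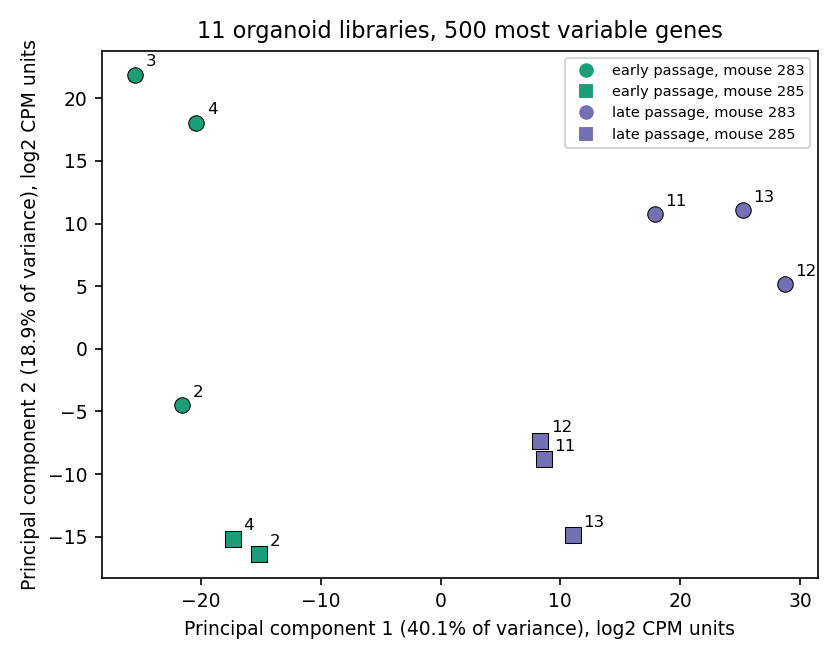
Principal components 1 (x axis) and 2 (y axis) of log2 CPM over the 500 most variable genes, 1 point per library, coloured by stage, shaped by animal and labelled with the passage number. Early libraries lie at negative and late libraries at positive values of component 1, which holds 40.1% of the variance.

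**Figure D2:**
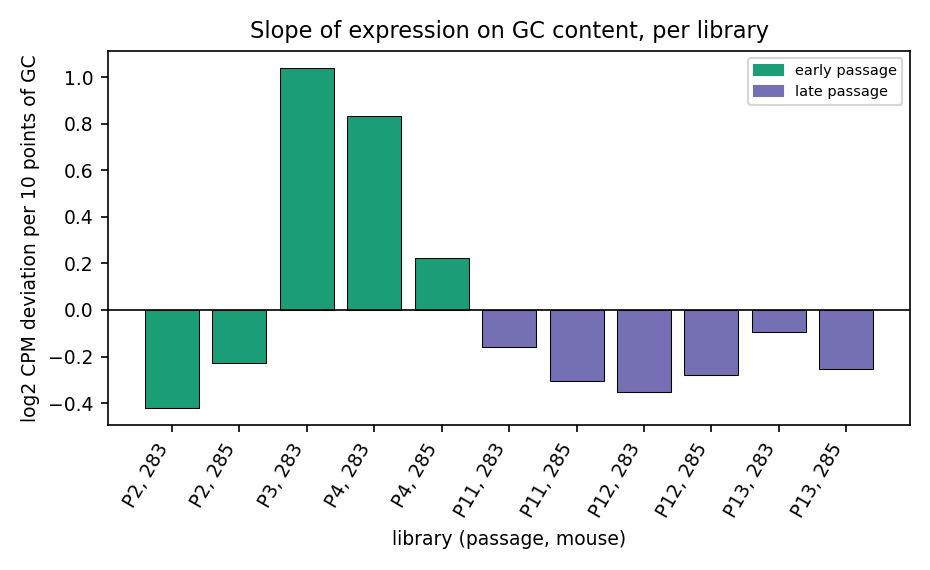
Slope of each library's log2 CPM deviation on GC content (y axis, log2 units per 10 points of GC) for the 11 libraries (x axis, passage and mouse), bars coloured by stage. Passages 3 and 4 of mouse_283 stand at 1.04 and 0.832, and the other 9 lie between -0.423 and 0.222.

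Among the largest rises late against early was Tfap2a, encoding transcription factor AP-2 alpha (ENSMUSG00000021359.8), which went from 2.62 ± 1.33 CPM (SD, n = 5) in early to 22.3 ± 7.53 CPM (SD, n = 6) in late libraries, a log2 rise of 3.17 (SE 0.28, adjusted p = 0.00036). Sox21 rose by 2.53 (SE 0.25, adjusted p = 0.000595) and the homeobox gene Meis2 by 2.06 (SE 0.27, adjusted p = 0.00249). Of the largest falls, the chymotrypsinogen gene Ctrb1 went from 110 ± 56.5 CPM (SD, n = 5) to 10.6 ± 8.99 CPM (SD, n = 6), a log2 change of -4.19 (SE 0.50, adjusted p = 0.00165). Lct, which encodes the brush border enzyme lactase, fell by 3.09 (SE 0.63, adjusted p = 0.0211) and Npl, of sialic acid breakdown, by 2.88 (SE 0.27, adjusted p = 0.000466). In all, 432 genes differed between late and early passages, 100 higher and 332 lower late, and 331 of them by more than a log2 change of 1. This balance turned without a low-count filter, with 1053 higher and 766 lower, and without passage 2 of mouse_283, with 2596 and 2276. The p-values measure the spread between libraries, with 2 animals behind them, and the labels give no sequencing or culture batch, so stage and batch cannot be told apart.

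The fixed rule, which requires the same direction in both animals, named further genes. Rises were Syt8 (log2 change 2.28), the monocarboxylate transporter family member Slc16a12 (2.14), the sulfotransferase family member Sult6b2 (1.98), the matrix protein gene Npnt (1.82), the adenylate cyclase gene Adcy8 (1.77), Fmnl2 (1.74) and the calcium-binding protein gene S100a6 (1.72), with adjusted p from 0.0053 for Slc16a12 to 0.0318 for Fmnl2. Falls were Ndufa4l2 (-4.33), Nrn1 (-4.06), Emid1 (-3.36), the potassium channel subunit gene Kcns3 (-3.25), the cytochrome P450 gene Cyp2d22 (-3.24), Pm20d1 (-2.86) and the actin-severing protein gene Scin (-2.63), with adjusted p from 0.000761 for Cyp2d22 to 0.0159 for Kcns3. Without passages 3 and 4 of mouse_283 the count was 697 genes, with 370 of the 432 called again in the same direction, and after the GC and length correction it was 966, with 394 called again. Leaving out passage 2 of mouse_283, which left only the 2 libraries with the steep GC trend as that animal's early set, gave 4872 genes, and leaving out any other single library gave from 173 to 435.

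**Figure D3:**
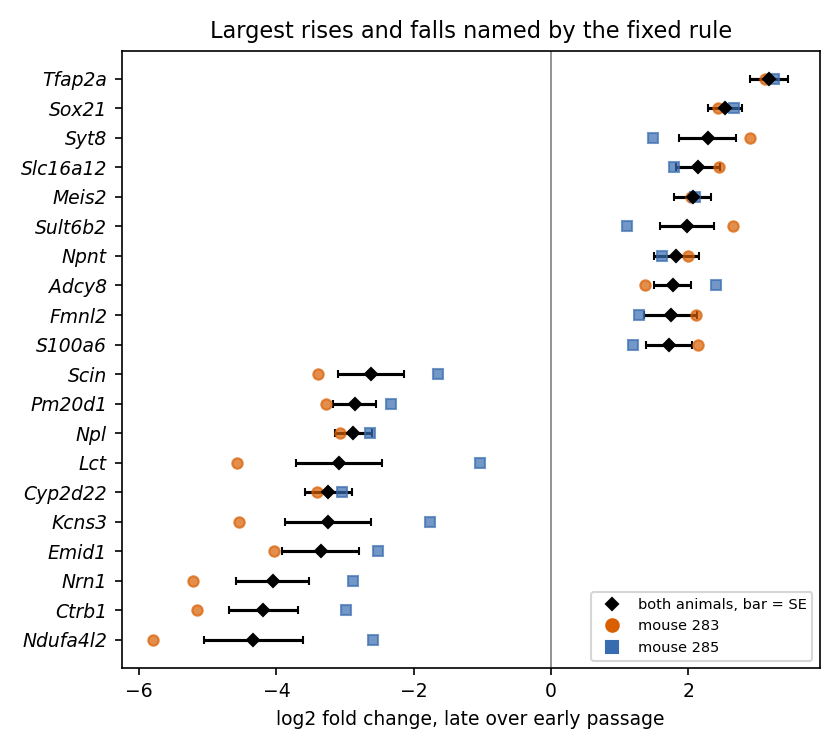
Log2 fold change of late over early passage (x axis) for the 10 largest rises and 10 largest falls (y axis, gene symbols). Diamonds give the fit over both animals with the SE as bars, circles mouse_283 alone and squares mouse_285 alone, from 3.17 for Tfap2a to -4.33 for Ndufa4l2.

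Genes of the interferon response were lower in late passages. Of 24 tested members, 11 fell and 0 rose, and 11 fell and 1 rose when adjusted over the list alone, with a median log2 change of -1.39. Irf7, the transcription factor that amplifies interferon signalling, went from 38.3 ± 11.3 CPM (SD, n = 5) to 8.82 ± 2.60 CPM (SD, n = 6), a log2 change of -2.08 (SE 0.20, adjusted p = 0.000466). Irf9, Dhx58 and Oas1a, which encode a subunit of the interferon-activated transcription complex, a viral RNA sensor and an antiviral enzyme, fell by 1.25, 1.57 and 1.92 (adjusted p = 0.00139, 0.00151 and 0.00241). The list was called lower by camera with its preset correlation (adjusted p = 1.94e-13) but not with an estimated one (adjusted p = 0.141 with an estimated correlation). Each late library had a lower mean over the list than each early library of the same animal. In mouse_283 the gap was narrow, with mean log2 deviations of 0.064 at passage 4 and 0.016 at passage 12, against 1.66 at passage 2. Without passages 3 and 4 of mouse_283 the median was -1.70, with passage 2 as the only early library of that animal. After GC correction the median was -1.32, with 11 of 24 tested members lower.

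Antigen presentation genes moved the same way. Of 17 MHC class I presentation genes, 4 fell and 0 rose (11 and 0 adjusted over the list alone), among them the peptide transporter gene Tap1 (log2 change -1.06, SE 0.19), the immunoproteasome gene Psmb8 (-2.41, SE 0.47, from 1.56 CPM), Tapbp (-0.80, SE 0.18) and H2-D1 (-0.84, SE 0.20), with adjusted p from 0.0109 to 0.0459. Of 8 MHC class II presentation genes, 4 fell and 0 rose (6 and 0 adjusted over the list alone), namely H2-Ab1 (-2.97, SE 0.52), H2-DMa (-1.41, SE 0.32), Ctss (-0.997, SE 0.22) and Lgmn (-0.74, SE 0.15), where H2-Ab1 was at 2.65 CPM or less on average. The class I and class II lists were called lower by camera (adjusted p = 0.000271 and 6.76e-05), each with adjusted p = 0.141 with an estimated correlation. NF-kB and antimicrobial genes were lower as a list (adjusted p = 0.00106, and 0.131 with an estimated correlation), with 2 of 18 lower and 0 higher (3 and 0 adjusted over the list alone), Lcn2 (-3.72, SE 0.84) and Reg3b (-1.70, SE 0.39), both with group means under 3 CPM. The change of Lcn2 came from mouse_283 (-5.07, SE 0.69), since in mouse_285 it was -0.10 (SE 1.00) at levels under 0.2 CPM. Members of the immune cell list summed to between 9.06 and 25.4 CPM per library, highest in passage 2 of mouse_283, and the pan-leukocyte gene Ptprc was at most 0.0345 CPM.

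Tuft cell markers fell in late organoids. All 13 tested markers had a negative fold change, 6 passed the test (10 adjusted over the list alone, 0 higher in either count), and the median log2 change was -1.20. The actin-binding protein gene Avil went from 7.89 ± 1.49 CPM (SD, n = 5) to 2.26 ± 0.489 CPM (SD, n = 6), a log2 change of -1.78 (SE 0.22, adjusted p = 0.00208). The taste-pathway channel gene Trpm5 fell by 1.20 (SE 0.27, adjusted p = 0.0315), and Sh2d6, at 1.13 CPM early, by 1.92 (adjusted p = 0.0395). Camera called the list lower (adjusted p = 4.33e-09), with adjusted p = 0.0706 with an estimated correlation. After GC correction the list's median was -1.16 with 5 members lower, and without passages 3 and 4 of mouse_283 it was -0.92 with 3 lower. Avil was called in both fits, Trpm5 only after GC correction and Sh2d6 in neither.

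Absorptive cell genes were lower as well. Of 30 enterocyte genes 6 fell and 0 rose (12 and 0 adjusted over the list alone), with the brush border peptidase gene Anpep going from 1610 ± 237 CPM (SD, n = 5) to 687 ± 227 CPM (SD, n = 6), a log2 change of -1.27 (SE 0.25, adjusted p = 0.0176). The glucose transporter gene Slc5a1 fell by 0.98 (SE 0.18) and the apolipoprotein gene Apoa1 by 1.48 (SE 0.32), with adjusted p = 0.0144 and 0.0291. The list was called by camera (adjusted p = 3.77e-05), with adjusted p = 0.272 with an estimated correlation. Lower members numbered 14 without passages 3 and 4 of mouse_283 and 10 after GC correction. Fatty acid oxidation and ketogenesis genes were lower as a list (adjusted p = 0.000271, and 0.141 with an estimated correlation), with 3 of 24 lower and 0 higher (7 and 0 adjusted over the list alone), among them Hadh (-0.72, SE 0.17) and the liver and gut transcription factor gene Creb3l3 (-1.29, SE 0.32). The hypoxia and glycolysis list was just past the threshold (adjusted p = 0.0487, and 0.495 with an estimated correlation), with Slc16a3 (-0.83, SE 0.20) and Ndrg1 (-0.61, SE 0.14) lower among 25 members, the same 2 and 0 adjusted over the list alone. Leaving out any of 6 libraries ended that list's call. Its median of -0.40 became -0.17 after GC correction, where it was not called (adjusted p = 0.0628), and -0.15 without passages 3 and 4 of mouse_283, where it was not called either (adjusted p = 0.05 as rounded).

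**Figure D4:**
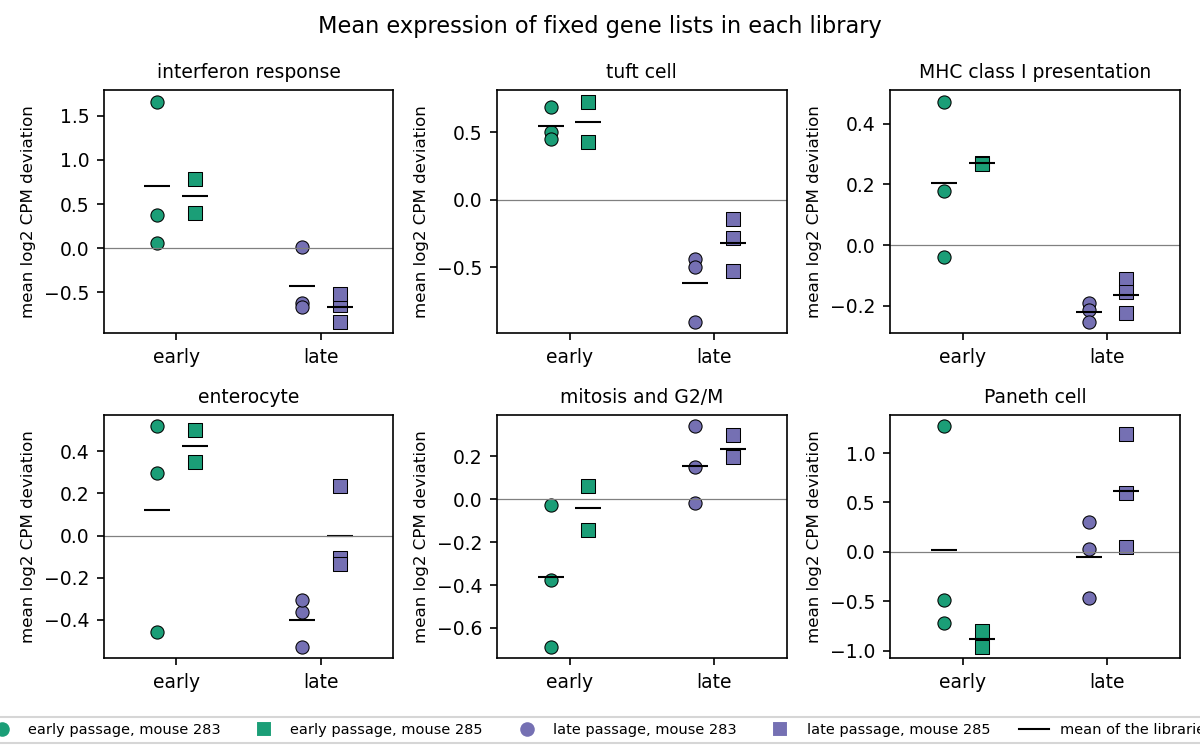
Mean log2 CPM deviation of the members of 6 fixed gene lists (y axis) in each library, by stage (x axis), with circles for mouse_283, squares for mouse_285 and a line at the mean of each animal and stage. Every late library lies below every early library of its animal for the interferon, tuft cell and MHC class I lists, while the Paneth cell list overlaps, with passage 4 of mouse_283 at 1.27.

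Lists that were higher late had few members past the test. All 13 mitochondrially encoded genes had a positive fold change (median 0.89), with mt-Co2 alone past the threshold (log2 change 1.21, SE 0.30, adjusted p = 0.0478) and 7 when adjusted over the list alone. Levels differed widely between these genes, with mt-Atp8 at 1.73 CPM or less and mt-Nd5 at 563.9 CPM or more in every library. The call of mt-Co2 was lost in 19 of 24 alternatives, which include the fits without passages 3 and 4 of mouse_283 and after GC correction, where 0 members of the list passed. Camera gave this list adjusted p = 3.77e-05, and 0.272 with an estimated correlation, and the median was 0.51 without passages 3 and 4 of mouse_283, which had low mitochondrial shares, and 0.37 after GC correction. The mitosis and G2/M list was higher (median 0.52, adjusted p = 0.00797, and 0.16 with an estimated correlation) with 0 of 25 members past the test in either count, and its median was 0.28 without passages 3 and 4 of mouse_283 and 0.21 after GC correction. The proliferation marker Mki67 was at 92.4 ± 56.2 CPM (SD, n = 5) early and 143 ± 66.1 CPM (SD, n = 6) late (adjusted p = 0.3). Of 26 p53 targets 1 rose, Eda2r (1.60, SE 0.29, adjusted p = 0.0126), and 1 fell, Tap1, and the list was called higher (adjusted p = 0.043, and 0.141 with an estimated correlation), with 1 higher and 2 lower adjusted over the list alone. Fold changes were positive for 20 members and negative for 6. The p53 target Cdkn1a had a negative fold change that did not pass, given below with the other cell cycle inhibitor gene. After GC correction 5 p53 targets were higher and 1 lower (adjusted p = 0.00217), and without passages 3 and 4 of mouse_283 2 were higher and 1 lower (adjusted p = 0.00388). Wnt targets and feedback genes were called higher (adjusted p = 0.0478, and 0.703 with an estimated correlation) with the cyclin gene Ccnd1 as the member that rose (0.82, SE 0.20) and 2 higher adjusted over the list alone. In the fit without passages 3 and 4 of mouse_283 5 Wnt members were higher (adjusted p = 1.05e-05), and after GC correction 3 were (adjusted p = 0.00275). Leaving out a single library ended the p53 call for 3 choices of library and the Wnt call for 7.

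Camera with its preset correlation thus called 12 of 33 lists, 4 higher and 8 lower. None of these held with an estimated correlation, and 10 held by fry, which tests whether a list's genes move on balance 1 way and compares them with no other genes. An exact permutation of the mean list score, which moved stage labels within each animal and was chosen after seeing the data, called 13 lists, 9 of the 12 among them with the same direction (two-sided, 200 rearrangements, smallest possible p = 0.005). The other 4 were the ileal identity and imprinted gene lists, lower late, and the Polycomb list, higher late (adjusted p = 0.0165 each), and the proximal identity list, higher late (adjusted p = 0.0381), none of which camera called with all libraries. The enterocyte, Wnt and hypoxia lists did not pass it (adjusted p = 0.088, 0.204 and 0.317).

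Enteroendocrine markers were not called as a list (adjusted p = 0.963) but single members changed in opposite directions. Chgb, encoding the granule protein chromogranin B, went from 224 ± 88.3 CPM (SD, n = 5) to 640 ± 68.2 CPM (SD, n = 6), a log2 change of 1.51 (SE 0.25, adjusted p = 0.00871), and the transcription factor gene Neurod1 rose by 1.42 (SE 0.31, adjusted p = 0.0302). The hormone genes Sst and Pyy fell by 1.88 (SE 0.37) and 2.21 (SE 0.49), with adjusted p = 0.0182 and 0.0305, Pyy from a level of only 1.22 CPM. Of 24 tested members 2 rose and 2 fell, and 7 rose and 7 fell adjusted over the list alone. The list was called higher without passages 3 and 4 of mouse_283 (adjusted p = 0.017, median 0.49), with 7 members higher and 2 lower, and after GC correction it was not (adjusted p = 0.877).

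The stem cell and DNA methylation genes fixed for naming did not pass the test with all libraries. Lgr5 was at 135 ± 72.0 CPM (SD, n = 5) early and 178 ± 57.1 CPM (SD, n = 6) late (log2 change 0.35, SE 0.36, adjusted p = 0.526), and Olfm4, another stem cell marker, at 164 ± 175 and 401 ± 333 CPM (adjusted p = 0.484). The DNA methyltransferase genes Dnmt1, Dnmt3a and Dnmt3b had log2 changes of 0.09, 0.12 and 0.17 with SE of 0.15, 0.24 and 0.20 (adjusted p = 0.714, 0.765 and 0.572). Uhrf1, which recruits Dnmt1, had a log2 change of -0.24 (SE 0.21, adjusted p = 0.46), and the dioxygenase gene Tet1 stood at 0.753 and 0.728 CPM (adjusted p = 0.977). None of the 25 members of the DNA methylation and demethylation list passed, in either count, and the list was not called (adjusted p = 0.218), while after GC correction 1 member was higher (adjusted p of the list 0.223). None of the 25 stem cell list members passed with all libraries. Without passages 3 and 4 of mouse_283, 4 of them were higher and the list was called higher (adjusted p = 7.75e-05, median 0.33), and after GC correction 2 were higher and the list was not called (adjusted p = 0.223). The cell cycle inhibitor genes Cdkn2a (log2 change 2.08, SE 0.74, adjusted p = 0.134, group means under 1 CPM) and Cdkn1a (-0.60, SE 0.18, adjusted p = 0.0882) did not pass either.

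Other lists were not called between late and early passages with all libraries. These were the stem cell (adjusted p = 0.183), Paneth cell (0.388), goblet cell (0.833), proximal identity (0.661), ileal identity (0.0558), colon identity (0.429), gastric identity (0.661), fetal-like and regenerative (0.472), senescence (0.832), DNA replication (0.388), Polycomb (0.266), imprinted gene (0.187), Notch (0.429), unfolded protein response (0.428), NRF2 (0.832), cholesterol synthesis (0.428), immediate early (0.429), immune cell (0.429) and neuron and glia (0.833) lists. Further lists were called by camera without passages 3 and 4 of mouse_283, a fit that has 1 early library of that animal. Only the preset correlation was used in that fit, while with all libraries the estimated one ended every late-against-early list call. Of these further lists, those higher late were the Paneth cell (adjusted p = 3.3e-10, 11 of 18 members higher and 1 lower), stem cell, DNA replication (0.000988), Notch (0.0113) and Polycomb (0.0355) lists. Those lower late were the ileal identity (0.00195), fetal-like (0.00569), imprinted gene (0.0178), immediate early (0.0355), unfolded protein response (0.0355) and fibroblast (0.0387, with 6 members then tested) lists. After GC correction the Notch (0.0135), ileal identity (0.0154) and Polycomb (0.0156) lists were called in the same directions, and the Paneth cell list was not (0.212). With all libraries the colon identity list had a median log2 change of 0.12 but a mean of -0.54 and a downward test direction. The proximal identity, gastric identity and goblet cell lists had medians of -0.08, -0.08 and -0.01 against means of 0.12, 0.22 and 0.02 and an upward direction. Fibroblast, endothelial, erythroid and sex-linked lists had fewer than 5 tested members. Single members that passed were Pdx1 (1.19, SE 0.23), Fgf15 (1.37, SE 0.31) and Gsta3 (1.07, SE 0.20) upward and Slc46a1 (-1.01, SE 0.23), Srxn1 (-0.79, SE 0.19), Tnfaip2 (-0.84, SE 0.18), Ereg (-4.53, SE 1.10), Grb10 (-3.49, SE 0.69) and Aqp8 (-4.03, SE 0.76) downward, with group means under 2 CPM for Fgf15, Ereg, Grb10 and Aqp8.

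Many calls of named genes near the threshold were lost when the processing changed. Among the genes named above, the late-against-early calls of Fmnl2, H2-D1, H2-DMa, Ctss, Lcn2, Reg3b, Trpm5, Sh2d6, Hadh, Creb3l3, Slc16a3, Ndrg1, mt-Co2, Ccnd1, Neurod1, Fgf15, Ereg, Slc46a1, Srxn1 and Tnfaip2 were each lost in at least 10 of 23 to 25 alternatives, mostly with a single library left out. Those of Creb3l3, Srxn1, Gsta3, Sh2d6 and mt-Co2 were lost after GC correction, and those of Fgf15, H2-DMa, Reg3b, Slc16a3, Trpm5, Sh2d6 and mt-Co2 without passages 3 and 4 of mouse_283. Tfap2a, Sox21, Meis2, Ctrb1, Npl, Irf7, Irf9, Dhx58, Oas1a, Avil, Chgb and Eda2r lost theirs in 1 alternative of 25. That was the counts summed per animal and stage without the animal as block, where no gene passed at all. All alternatives refit libraries of the same lines, so they do not test replication over animals.

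Most genes called late against early in mouse_283 changed in the same direction in mouse_285. In mouse_283, with 3 late and 3 early libraries, 201 genes differed, 47 higher and 154 lower. In mouse_285, with 3 late and 2 early, 0 genes passed edgeR's test, with 762 genes at an unadjusted p under 0.05 and 74 genes by DESeq2. Both contrasts came from a fit whose spread was estimated over all libraries, so the 0 does not describe mouse_285 alone. After GC correction some genes passed in mouse_285, as listed further below. Of the 201 genes, 191 (95%) had the same sign in mouse_285, and 145 had that sign with an unadjusted p under 0.05. Their median log2 change was 2.44 in mouse_283 and, signed by mouse_283, 1.23 in mouse_285. These genes were picked because they passed in mouse_283, which raises their size there. The gap between the medians therefore does not show a weaker change in mouse_285. Across 10052 genes of at least 5 CPM the fold changes of the animals had Pearson's r of 0.70, and 0.58 after GC correction, where genes are not independent replicates. Irf7 changed by -1.97 in mouse_283 and -2.23 in mouse_285, Avil by -1.79 and -1.77, Tfap2a by 3.12 and 3.24, and Lct by -4.57 and -1.04.

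The line of mouse_285 had lower expression than mouse_283 of genes known from the upper intestine, and 11 genes in all passed the test, each lower in mouse_285. Pdx1, a homeobox gene of duodenum and pancreas (ENSMUSG00000029644.6), was at 38.3 ± 20.2 CPM (SD, n = 6) in mouse_283 and 7.79 ± 2.89 CPM (SD, n = 5) in mouse_285, a log2 difference of -2.31 (SE 0.24, adjusted p = 0.00198). The iron exporter gene Slc40a1 was at 166 ± 113 and 19.2 ± 7.82 CPM (-3.02, SE 0.40, adjusted p = 0.0152) and the alkaline phosphatase gene Akp3 at 168 ± 82.2 and 26.3 ± 9.54 CPM (-2.74, SE 0.29, adjusted p = 0.002). The transcriptional coactivator gene Wwtr1 (-2.05), the glycine cleavage gene Amt (-1.32) and Eps8l1 (-1.24) were the other genes named by the rule. Below its level of 5 CPM, and so chosen after their values were seen, stood Nkx6-3, a transcription factor gene of the stomach and duodenum (-5.23, SE 0.48, adjusted p = 0.00114), Sftpd (-5.90), Wnt4 (-2.88) and Fgd3 (-1.68). The gap of Sftpd lay in early libraries, at 3.91 to 6.36 CPM in mouse_283 and 0 in mouse_285, with late levels of 0.405 CPM or less. That of Wnt4 lay mainly in late libraries, at 4.55 to 8.60 CPM against 0.504 to 0.874 CPM.

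Several fixed lists differed between the animals. The proximal small intestine identity list was lower in mouse_285 (adjusted p = 2.2e-09, and 0.00498 with an estimated correlation), with 2 of 10 members lower and 0 higher (3 and 0 adjusted over the list alone), Pdx1 and Slc40a1. The fetal-like and regenerative epithelium list (median log2 difference -0.98) had adjusted p = 2.14e-18, and 0.0462 with an estimated correlation, with 0 of 20 members past the test and 9 lower adjusted over the list alone. Ly6a, a marker of that state, was at 46.5 ± 20.5 CPM (SD, n = 6) and 16.0 ± 10.2 CPM (SD, n = 5), with adjusted p = 0.122. Senescence and secretory factor genes were also lower as a list (adjusted p = 0.00103, and 0.0462 with an estimated correlation), with 0 of 19 members past the test and 1 lower adjusted over the list alone. The median of this list was -0.49, and it was -0.27 after GC correction and -0.72 without passages 3 and 4 of mouse_283. Fry called only the proximal list. The other 10 called lists were lost with an estimated correlation, with adjusted p from 0.223 to 0.472, and were higher in mouse_285 for the enterocyte, enteroendocrine and mitochondrially encoded lists and lower for the goblet cell, hypoxia, interferon, gastric, unfolded protein, NRF2 and immediate early lists. Without passages 3 and 4 of mouse_283, 107 genes differed, which included all 11, and after GC correction 28 differed, with 10 of the 11 called again. Leaving out passage 4 of mouse_285 or any single late library left 3 or 4 genes, leaving out passage 2 of mouse_285 left 6, and leaving out passage 2 or passage 3 of mouse_283 gave 74 and 18. Akp3 and Nkx6-3 were called in every alternative run, and Pdx1 in all but 1 of 21. Amt, Eps8l1, Wwtr1, Slc40a1, Sftpd, Wnt4 and Fgd3 lost their calls in 13, 12, 10, 8, 12, 10 and 11 of 20 or 21 alternatives. The 2 animals are single donors, so this comparison measures these lines.

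No gene passed edgeR's test of the interaction, which asks whether the change from early to late differed between the animals, with 302 genes at an unadjusted p under 0.05 and 16 genes by DESeq2. The smallest adjusted p was 0.137, for Lct, whose change was more negative in mouse_283 by 3.52 log2 units (SE 0.48). As lists, enteroendocrine markers changed more positively in mouse_285 (median difference 0.98, adjusted p = 4.1e-12, and 0.0372 with an estimated correlation), with 0 of 24 members past the test, and 2 higher and 1 lower adjusted over the list alone. The median difference of this list was 0.58 without passages 3 and 4 of mouse_283. The glucagon gene Gcg was at 28.7 ± 6.71 CPM (SD, n = 3) early and 3.28 ± 2.10 CPM (SD, n = 3) late in mouse_283, and at 41.1 ± 0.474 CPM (SD, n = 2) and 36.3 ± 1.83 CPM (SD, n = 3) in mouse_285. Gip, of another gut hormone, was at 82.9 and 33.2 CPM in mouse_283 and at 50.1 and 123 CPM in mouse_285. Its early mean in mouse_283 came from passages 3 and 4, with the steep GC trend, at 122 and 92.7 CPM, against 34.3 CPM at passage 2. The transcription factor gene Pax6 went the other way, at 1.65 and 14.5 CPM in mouse_283 and 1.70 and 2.37 CPM in mouse_285.

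The Paneth cell list had a larger median difference and a smaller p with the preset correlation, but was lost with an estimated one (median 1.70, adjusted p = 9.11e-15, and 0.401 with an estimated correlation), with 0 of 18 members past the test in either count. Mmp7, a Paneth cell protease gene, was at 26.2 ± 9.11 and 8.35 ± 3.88 CPM (SD, n = 3 each) early and late in mouse_283. In mouse_285 it was at 8.80 ± 1.33 CPM (SD, n = 2) and 13.4 ± 6.38 CPM (SD, n = 3). The Paneth list was not called without passages 3 and 4 of mouse_283 (adjusted p = 0.136, median 0.39). The stem cell, DNA replication, neuron and glia, enterocyte and Wnt lists were called in the same direction and lost with an estimated correlation (adjusted p = 0.626, 0.401, 0.356, 0.777 and 0.777), and fry called none of the 7.

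No gene passed edgeR's test of a trend with passage number, fitted as a slope shared by both stages (0 genes, 911 at an unadjusted p under 0.05, 0 by DESeq2, smallest adjusted p 0.596). The power of this test was not simulated, so it does not show stable expression inside a stage. The interferon list score was 1.66, 0.375 and 0.064 at passages 2, 3 and 4 of mouse_283. In mouse_285 it was 0.782 and 0.397 at passages 2 and 4. Xist, expressed from the inactive X chromosome in females, was read in all 11 libraries, between 76.9 and 1050 CPM of gene reads, and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 0 reads in each, which allows at most 0.20 CPM at 3 counts, a limit for counting error only. Among markers of other cell types, the fibroblast and smooth muscle list summed to between 12.6 and 53.2 CPM, highest in passage 2 of mouse_283, the endothelial list to between 6.56 and 18.3 CPM and the erythroid list to at most 0.515 CPM. The neuron and glia list summed to between 15.5 and 40.4 CPM, above the endothelial list in every library, with Ret as its highest member at up to 33.4 CPM. H2-D1, Akp3, Cyp2d22, mt-Co2 and the Paneth cell defensin genes have near-identical relatives or nuclear copies that share reads, so their values are less certain.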

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

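The tests of GC content, of abundant genes, of immune cells and of intestinal position, and the comparisons with other splits of the libraries, were chosen after the results were seen.

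In 17 of 158 sets of values a single library lay far from the rest of its stage, where chance gives about 1 in 20 sets. Passage 4 of mouse_283 accounted for 9 of them, all as mean list scores on the log2 scale. It was the highest early library for the Paneth cell (1.27), Wnt (0.679), Notch (0.242) and DNA replication (0.125) lists. It was the lowest for the enterocyte (-0.459), unfolded protein response (-0.363), immediate early (-0.335), ileal identity (-0.196) and cholesterol synthesis (-0.142) lists. Passage 3 of mouse_283 was highest for the goblet cell list (0.445) and for Ndufa4l2 (6.17 as log2 of CPM plus 1), and passage 2 of mouse_283 was lowest for the MHC class II list (-0.169) and highest for Lct (5.82). Among late libraries, passage 12 of mouse_285 was highest for DNA replication (0.241), passage 13 of mouse_285 lowest for gastric identity (-0.64), and passage 12 of mouse_283 lowest for Dnmt1 (7.24) and Uhrf1 (6.45).

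Passages 3 and 4 of mouse_283 stood apart from the other 9 libraries over all genes, with median correlations of 0.919 and 0.935. A few genes taking most of the reads were argued against, since the 10 most abundant genes held 8.66% in passage 3, within the range of 7.69% to 9.6% of the others. A trend on GC content and transcript length is a candidate explanation: after its correction the lower of their median correlations was 0.943, within 1 SD (0.0078) of the lowest other library at 0.948. Whether library preparation or a state of these cultures produced the trend stays open, and no biological explanation was tested.

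The change from early to late differed between the animals for 7 lists by a test of the interaction with camera's preset correlation. Adjusted p was 9.11e-15 for the Paneth cell, 4.1e-12 for the enteroendocrine, 0.00196 for the stem cell, 0.00657 for the DNA replication, 0.0268 for the neuron and glia and 0.0416 for both the enterocyte and the Wnt list, each with a more positive change in mouse_285. With an estimated correlation only the enteroendocrine list was called (adjusted p = 0.0372), the others having 0.356 to 0.777, and fry called none of the 7. Without passages 3 and 4 of mouse_283 the enteroendocrine list had adjusted p = 0.000324 and the enterocyte list 0.00898 with the preset correlation. The Paneth cell, stem cell, DNA replication, neuron and glia and Wnt lists then had 0.136, 0.0531, 0.549, 0.123 and 0.475, with medians of 0.39, 0.27, 0.13, 0.78 and 0.09 in place of 1.70, 0.41, 0.40, 1.10 and 0.26. That fit has only 1 early library of mouse_283, assumed to vary like the others, so a lost call with a median largely retained, as for the neuron and glia list, does not show that these libraries made it.

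Interferon response genes were lower in late passages in both animals. GC content and transcript length as the whole cause were argued against by a median of -1.32 after correction, against -1.39 before it, with an interquartile range of 1.26 among members. Immune cells left in early cultures were argued against as well: 1 of 20 immune markers, Itgam, averaged at least 5 CPM in early libraries, and Ptprc was at most 0.0345 CPM in any library. Unlabelled batches that follow stage stay open and cannot be told apart from passage. A change of the epithelium with time in culture also stays open, as a hypothesis.

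Proximal small intestine identity genes were lower in mouse_285. After GC and length correction the list kept its direction with adjusted p = 4.24e-13, which argues against that trend as the whole cause. A more distal piece of intestine in mouse_285 could not be decided: the ileal identity list had a median of 0.12 and adjusted p = 0.583, and a p that misses the threshold does not show equal values. The protocol text describes dissection of upper and lower small intestine and of colon, and the labels, which give small intestine for every library, name no part of it, so region, donor and age stay open and untested.

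Other splits of the 11 libraries into the same group sizes were fitted, 100 in each comparison, the real one included. For late against early, 3 of 100 gave at least the real 432 genes, a share under 0.05, although the highest other split gave 4716. The larger ones set passages 3 and 4 of mouse_283 against the other libraries of that animal, which points to that structure of the samples, and among 47 splits with the same balance of animals the highest other gave 0. For the animals, 1 of 100 gave at least 11 genes (highest other 3). All these splits treat libraries as exchangeable, although those of an animal are successive passages of 1 line. A small share therefore places the real grouping among groupings of these libraries, and does not exclude chance between lines. Within mouse_283, 10 splits are too few for a share under 0.05 (real 201, highest other 0).

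By this measure chance cannot be excluded for the number of called lists: 21 of 100 splits gave at least the 12 lists of late against early (highest other 19) and 8 of 100 at least the 13 lists of the animals (highest other 15). By unadjusted camera p, 9 of 100 splits gave a p for the interferon list as small as the real 5.87e-15 (smallest other 6.42e-29), so chance cannot be excluded by this measure. An exact permutation of mean list scores within each animal asks a narrower question, and gave the interferon, tuft cell, MHC class I, MHC class II, NF-kB, fatty acid oxidation and mitosis lists p = 0.005 each (two-sided, adjusted p = 0.0165), the smallest that 200 rearrangements can give. For the tuft cell list 2 of 100 splits gave as small a camera p (real 2.62e-10, smallest other 3.35e-11). For the proximal identity list between animals 1 of 100 did (real 1.33e-10, smallest other 1.7e-05). Both lists were chosen after their p-values were seen, and the shares are not adjusted for that choice. As the libraries are also not exchangeable, these shares do not exclude chance.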

How the results depend on the processing

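Fits without passages 3 and 4 of mouse_283, the GC and length correction and the list-score permutation were chosen after the results were seen. Where a reason is not given, the cause was not tested.

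With RLE factors and without mitochondrially encoded genes, every count of genes and lists was within 1.5 times its reported value. Library totals moved the median log2 change of all genes from -0.021 to 0.11 late against early, and gave 4 genes between the animals and 132 within mouse_283. Without a low-count filter there were 1819 genes late against early (57.9% higher), 207 between the animals, 65 for the interaction, 1446 within mouse_283 and 114 within mouse_285. The filter at 5 CPM, which tested fewer genes, gave 236, 4 and 91 for late against early, the animals and mouse_283. A strand column gave 6 between the animals, 1 for the interaction and 3 within mouse_285. DESeq2 gave 1343 (36.9% higher), 126, 16, 736 and 74 in the order used for the missing filter. The model without the stage gave 2 genes between the animals.

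Counts summed per animal and stage gave 2396 genes with the animal as block (58.8% higher) and 0 without this block by edgeR, with 3105 at an unadjusted p under 0.05. With a single sum per animal and stage, the fit with the block has almost no replication left to measure the spread. Its count therefore cannot be set against that of single libraries. With single libraries and no replicate block there were 400 genes, 355 of them among the 432 with the same sign. Without passages 3 and 4 of mouse_283 there were 697, 107, 5, 932 and 317 genes, 23 lists late against early and 3 for the interaction. GC and length correction gave 966 (37.5% higher), 28, 1, 543 and 34 genes. An estimated correlation left 0 lists late against early, where the preset one had 12 and fry 13, with 3 between the animals and 1 for the interaction, and fry left 1 and 0. Component 1 of all tested genes held 46.9% of the variance and no longer separated stage.

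Leaving out each library in turn gave 173 to 4872 genes late against early. The count was 4872 without passage 2 of mouse_283, 173 without passage 4 of mouse_285, and 198, 177 and 186 without passages 11, 12 and 13 of mouse_283, against 232, 207 and 259 without those of mouse_285. Ranges were 3 to 74 for the animals, 0 to 2314 for the interaction, 36 to 7694 within mouse_283 and 0 to 58 within mouse_285, each highest without passage 2 of mouse_283. Lists ranged from 9 to 14 late against early, 9 to 15 between the animals and 3 to 10 for the interaction, and component 1 from 36.2% to 46.2%. Where an early library of mouse_285 was left out, the lone early library of that animal was assumed to vary like the others.

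The trend with passage number had 0 genes by edgeR under every alternative run and 0 by DESeq2, with 911 at an unadjusted p under 0.05. Of 1779 values of 72 named genes late against early, 1383 kept direction and side of the threshold, 373 lost the threshold, 12 gained it and 11 reversed. Reversals were in genes that had not passed. Dnmt3a had a log2 change of -0.00914 without passage 3 and -0.197 without passages 3 and 4 of mouse_283, and Uhrf1 had 0.117 in the latter. Tet1 had 0.0197 with library totals, 0.0269 without a filter, 0.0443 and 0.0456 in summed counts with and without the block, and 0.126, 0.181 and 0.868 without passage 13 of mouse_285, passage 12 of mouse_283 and passage 2 of mouse_283. With single libraries left out Tet1 ranged from -0.307 to 0.868 and Dnmt3a from -0.00914 to 0.33. Of 298 values of the 12 lists late against early, 255 kept their call and 43 lost it. Between the animals, 77 of 268 values of 13 genes lost their call, in 8 of the genes, and for 13 lists 238 values kept the call and 45 lost it, in 12 of the lists, and for the interaction 39 of 146 values of 7 lists did. The Wnt list's interaction reversed without passage 4 of mouse_283 (adjusted p = 0.927, in a range from 2.96e-06 over single libraries left out). Depth of 15114132 to 28949911 reads limits genes under about 0.20 CPM.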

Other observations

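The genes here were chosen after their values were seen, and the corrected fold changes come from the GC and length correction, also chosen then.

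Genes known from the exocrine pancreas were read in these intestinal cultures, of which Clps and Pnliprp2 are also members of the fixed Paneth cell list. Late against early, Ctrb1 had a log2 change of -4.19 (SE 0.50, adjusted p = 0.00165), Sycn of -2.03 (SE 0.40, adjusted p = 0.0191) and Pdia2 of -2.41 (SE 0.27, adjusted p = 0.00119). Clps was at 35.6 ± 24.9 CPM (SD, n = 5) early and 40.8 ± 11.4 CPM (SD, n = 6) late, Pnliprp2 at 80.4 and 48.5 CPM and Cela1 at 26.8 and 21.8 CPM, and none of these passed the test. Prss2, Cpa1, Ctrc, Amy2a5 and Amy2b had 0 counted reads in all 11 libraries. This allows at most 0.20 CPM each, a limit for counting error only. Multimapping reads were left out of the counts, so the limit does not cover reads shared with a near-identical gene.

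Selenoprotein genes differed in whether correction changed them. Gpx1 had a log2 change of 0.90 (SE 0.28, adjusted p = 0.1) before and 1.29 (SE 0.16, adjusted p = 0.00133) after correction, Selenow 1.29 and 1.71 (adjusted p = 0.0807 and 0.00149), Selenoh 0.93 and 1.10 (adjusted p = 0.118 and 0.0089) and Selenom 0.83 and 1.28 (adjusted p = 0.148 and 0.000688). Sephs2 had -0.74 and -0.55 (adjusted p = 0.023 and 0.0152). Gpx4 and Msrb1 had -0.43 and -0.37 before and -0.02 each after, Txnrd1 0.25 and 0.20 and Selenof 0.34 and -0.04, with a change of sign, and these did not pass in either fit.

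Spp1 was read in 3 libraries, with 40.9 CPM as its highest value in passage 2 of mouse_283 and 0 reads in the other 8. Fn1 was highest in the same library, at 25.8 CPM, and averaged 0.0396 CPM late (log2 change -6.73, SE 1.33, adjusted p = 0.0182). That change came from mouse_283, at 0.581 to 25.8 CPM early, since in mouse_285 Fn1 was at most 0.167 CPM in any library, near the floor. Wnt4 was at 0.293 ± 0.193 CPM (SD, n = 5) early and 3.89 ± 3.78 CPM (SD, n = 6) late (log2 change 3.60, SE 0.47, adjusted p = 0.00246), with late levels of 4.55 to 8.60 CPM in mouse_283 and 0.504 to 0.874 CPM in mouse_285.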
